A study of Homo sapiens with 8 samples.

How the data were processed

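The series measured transcript levels in 786-O cells, a VHL-deficient clear cell renal carcinoma line, as cells labelled parental and as cells labelled HIF2a-null. The growth protocol, worded alike for all 8 samples, speaks of null cells alone, so genotype was taken from the titles, source names and characteristics. Cells received DMSO or PT2399, an inhibitor of HIF2a, at 2 uM for 24 h or 48 h. Each combination of genotype, treatment and time was measured on 1 array, 8 in all. Per the series description, the parental and null cells were handled in separate experiments, so genotype and experiment cannot be told apart in any direct comparison of the 2 genotypes.

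Per the labels' protocols, total RNA was extracted with Trizol and 100 ng was turned into biotinylated sense-strand DNA with an Affymetrix whole-transcript kit. The deposited values are probe set intensities on a linear scale, 1 value for each of 33252 probe sets per array. The methods of background correction, summarisation and scaling, and whether both experiments were scaled together, are not given in the sources used here. Every array had a mean intensity between 437 and 463, and the median lay between 99.4 and 133.8. Between 51 and 103 probe sets per array stood at exactly 1, and the lowest value was 0.81.

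Log2 of the deposited intensities was taken before every test, because the design written in advance had assumed log2 values. Gene names came from the platform annotation and were updated through Entrez identifiers against the GRCh38.p14 RefSeq gene table. Of 19460 probe sets with 1 gene, 19429 matched by Entrez identifier and 31 kept the older name. A further 1754 probe sets carried several genes and 12038 were unnamed here, and none of these was used for a named gene. No genomic coordinates are given, because the assembly behind the annotation is not named. A gene was represented by its probe set with the highest mean log2 value over the 8 arrays. Of 18417 genes, the 11050 at or above the percentile 40 of the mean entered the tests, a limit of 6.88 on the log2 scale or an intensity of 118.

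The comparisons were fitted with limma 3.58.1 in R 4.3.3, by lmFit and eBayes. A single model over the 8 arrays held a level, a time term and a PT2399 term for each genotype, which left 2 residual degrees of freedom. The 24 h and 48 h pairs therefore served as the repeats of a treatment effect. A p-value from this model measures the spread between those pairs, which can hold true differences between times as well as technical variation. The parental effect, the null effect and their difference were taken from the same model, with Benjamini-Hochberg adjustment over 11050 genes and a threshold of 0.05. Genes at least 2-fold changed in the same direction at both times were also counted, with no p-value. The number of arrays limits the precision throughout.

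A set of 20 gene lists was fixed in advance from general knowledge of VHL-deficient kidney cancer cells, hypoxia, growth, metabolism and stress, and no list was chosen on these samples. The 19 lists with at least 3 members above the filter were tested with camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run as alternatives, the former with statmod 1.5.0 installed. At the preset correlation camera takes its degrees of freedom from the number of genes. With an estimated correlation it takes them from the residual degrees of freedom of the arrays. A call lost there can therefore reflect the few arrays as well as correlated members. The list of endothelial and leukocyte markers was tested only without the filter, with 16 of its 20 genes below the filter and 2 above it. For single pairs of arrays, a list median was placed among 10000 random lists of the same size matched on mean expression. Members were also adjusted over the list alone.

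The genes named were set by a rule. It took the 12 largest rises and falls among genes past the threshold or, where none passed, the 5 largest in each direction with 1 direction at both times. It also took up to 4 leading members of each list and 14 fixed genes of the HIF pathway and its targets. CA9, which is among the 14, was not analysed here, and not all of the others are reported here. Genes known only by a locus or open reading frame name, small RNAs and members of near-identical families were counted but not named under this rule. These choices were made before the data were examined. Not every gene the rule allows is named. Values of single genes under the alternatives are given for the genes named in the text, a restriction made after a wider set had been seen, in which more genes changed sign.

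The procedure was tested on simulated data with 11050 genes, with normal noise drawn independently for each gene from spreads already shrunk by eBayes. Such spreads vary less between genes than the measured ones, so that the simulated power may be too high. With all 8 arrays, the parental test called 14% of genes changed by 1 on the log2 scale and 97% of those changed by 2, with 9 unchanged genes called. With the parental arrays alone it called 100% at either size, and 22 unchanged genes. Without a simulated shift camera called 0 of 19 lists. The simulated genes were uncorrelated, so that false list calls from correlated members could not appear. In the measured data EGLN3, at -2.64 in parental cells, was not called with all 8 arrays, nor with the parental arrays alone (limma adjusted p = 0.083).

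Alternatives covered the filter, the choice of probe sets, quantile normalization, centring of each array, the eBayes prior, the time term, the arrays entering the fit and the removal of each pair of arrays. Alternatives chosen after seeing the data were a floor of 32 on intensity, genes filtered within a genotype, and list tests with the parental arrays alone, without the null 48 h arrays, after centring of each array or without a time term.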

Results

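Transcript levels were measured on 8 whole-transcript arrays of 786-O cells, a clear cell renal carcinoma line without functional VHL, the protein that marks HIF alpha subunits for degradation. Parental cells and cells labelled HIF2a-null were treated with DMSO or with 2 uM PT2399, which keeps HIF2a from pairing with its partner ARNT, for 24 h or 48 h. There was 1 array per genotype, treatment and time, so that each effect rests on 2 pairs of arrays, at 24 h and at 48 h. Errors are standard errors (SE) from a single limma model over the 8 arrays unless a fit is named. They pool the spread of both genotypes, so that differences between the null pairs enter the errors of parental values. The median SE of a parental effect was 0.27 in this model and 0.14 in a fit on the parental arrays alone. Values are log2 differences of the deposited intensities.

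EPAS1, which encodes HIF2a, had an intensity of 1277 at 24 h and 1010 at 48 h in parental DMSO cells, against 650 and 585 in null DMSO cells. The parental level was 1.96 times the null level at 24 h and 1.73 times at 48 h. Where the probes lie relative to the edit is not given in the sources used here, and a disrupted gene can still be transcribed, so these levels check the labels only in part. With PT2399 the EPAS1 intensity was 1519 and 1304 in parental cells and 682 and 722 in null cells.

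The first comparison asked which transcripts respond to HIF2a inhibition in parental cells. Known HIF2a-linked targets were the lowest group. EGLN3, a prolyl hydroxylase that marks HIF alpha subunits, was 6.23-fold lower with PT2399 (log2 -2.64, SE 0.34, 2 pairs), going from an intensity of 863 to 95.2 at 24 h and from 566 to 132 at 48 h. NDRG1, a hypoxia-responsive gene, was 5.15-fold lower (-2.36, SE 0.25), and ADM, which encodes the vasodilator peptide adrenomedullin, was 4.63-fold lower (-2.21, SE 0.24). CCND1, the G1 cyclin D1, stood at -1.80 (SE 0.29), SLC2A1, the glucose transporter GLUT1, at -1.50 (SE 0.23), and VEGFA, the main angiogenic growth factor, at -1.49 (SE 0.34).

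Of the 18 measured genes of the HIF2a-linked list, 13 were lower and 5 higher, with a median of -0.61 (camera adjusted p = 3.0e-20). The camera call was lost with an estimated correlation (adjusted p = 0.18), and the fry adjusted p was 0.051. Adjusted over the list alone, 9 members fell by limma's moderated test: EGLN3, NDRG1, ADM, CCND1, TGFA, SLC2A1, VEGFA, SLC7A5 and PLIN2. Adjusted over all 11050 genes, 0 of them passed. TGFA, a ligand of the EGF receptor, stood at -1.53 (SE 0.36), SLC7A5, a leucine transporter subunit, at -1.24 (SE 0.27), and PLIN2, a lipid droplet coat protein, at -0.85 (SE 0.23). Other members stayed near 0, such as LOX, a collagen crosslinking enzyme, at 0.02 (SE 0.23) and CITED2, a transcriptional co-regulator, at -0.02 (SE 0.34), both of which changed sign under another scaling of the arrays. At 24 h alone the list median was -0.68 and at 48 h alone -0.59, each below all of 10000 random lists.

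**Figure D1:**
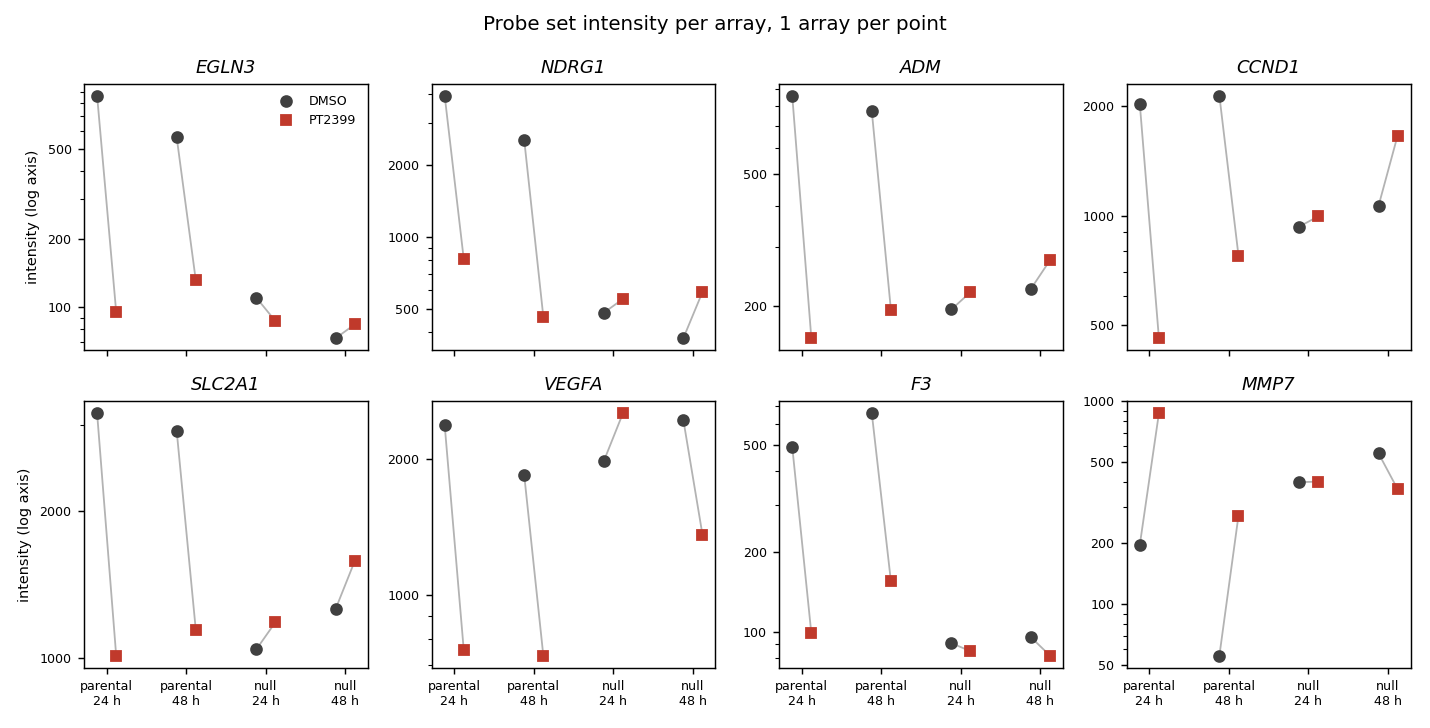
Probe set intensity on a log axis for 8 genes, 1 point per array, with circles for DMSO and squares for PT2399 and a line joining each pair. EGLN3 went from 863 to 95.2 at 24 h in parental cells, while its 4 null arrays lay between 73 and 110, and MMP7 went from 196 to 873 at 24 h in parental cells.

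At both times 28 genes were at least 2-fold lower and 5 at least 2-fold higher in parental cells, where independent times would give 0.218 and 0.0757. Of the 28, 7 belonged to the HIF2a-linked list against 0.0456 by chance (Fisher's exact test, one-sided p = 9.29e-15). That test counts genes as independent, although all were read on the same 2 pairs of arrays, so its p-value does not measure the spread between cultures. Genes outside that list, named because they met this count, included IRS2, an adaptor of the insulin receptor, at -2.52 (SE 0.39), and F3, the coagulation initiator tissue factor, at -2.21 (SE 0.23). Others were SEMA6A, a semaphorin, at -1.74 (SE 0.26), EDN1, the vasoconstrictor endothelin-1, at -1.56 (SE 0.32), and STC1, stanniocalcin 1, at -1.42 (SE 0.27). HILPDA, a hypoxia-induced lipid droplet protein, stood at -1.60 (SE 0.39), and APOL1, an apolipoprotein, at -1.44 (SE 0.23). The 5 higher genes were MMP7, a matrix metalloprotease, at 2.22 (SE 0.26), CLDN2, a tight junction protein, at 1.66 (SE 0.23), COL14A1, a collagen, at 1.51 (SE 0.30), AKR1B10, an aldo-keto reductase, at 1.26 (SE 0.44), and IL18, a cytokine, at 1.05 (SE 0.67). IL18 was 1.04 at 24 h and 1.06 at 48 h in parental cells, and its SE also holds the null pairs, at 0.22 and -2.82. RBM14, an RNA-binding protein, was 2.51 at 24 h and 0.07 at 48 h in parental cells.

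Over all 11050 genes, limma on the 8 arrays called 0 genes, with a lowest adjusted p of 0.455. An unadjusted p under 0.05 was found for 130 genes, 77 lower and 53 higher, fewer than the 552.5 that chance alone would give. The fit on the 4 parental arrays alone, planned as an alternative, called 4 genes and had 865 with an unadjusted p under 0.05. By that limma fit NDRG1, F3 and ADM fell and MMP7 rose, with SE 0.14 for NDRG1, F3 adjusted p = 0.0286 and ADM adjusted p = 0.0446. On simulated data the same fit called more unchanged genes than its threshold allows, so these 4 calls are less certain than their adjusted p-values. Without either null pair of arrays, when the parental pairs alone set the spread, the count was also 4, and without the parental 48 h arrays it was 2, EGLN3 and IRS2, when the parental effect rests on 1 pair and the null pairs set the spread.

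Genes of the glycolysis and HIF1a-linked hypoxia list were also mostly lower, though by less than the cell cycle lists described below. The list is named from general knowledge, and HIF1a protein and its activity in these cells were not measured. Of 25 measured, 20 were lower and 5 higher, with a median of -0.21 (camera adjusted p = 3.6e-07, and adjusted p = 0.28 with an estimated correlation). The lowest were DDIT4, a stress-induced inhibitor of mTORC1, at -1.22 (SE 0.28), CA12, a carbonic anhydrase, at -1.05 (SE 0.24), ENO2, an enolase, at -0.86 (SE 0.35), and HK2, hexokinase 2, at -0.70 (SE 0.27). Adjusted over the list alone 0 members passed in the 8 arrays by limma, 4 had an unadjusted p under 0.05, and 4 passed in the parental arrays. The glycolytic enzymes PGK1 at -0.06 (SE 0.27) and LDHA at -0.22 (SE 0.38) were within their errors of 0. The HIF pathway genes HIF1A at 0.43 (SE 0.38), ARNT at 0.07 (SE 0.25) and VHL at 0.09 (SE 0.24) were close to their errors or within them, with ARNT and VHL below 0 after centring of each array on its median. The list of 12 HIF pathway components had a median of 0.10 (camera adjusted p = 0.53).

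The cell cycle lists were lower in parental cells. All 31 measured G1/S and DNA replication genes were lower at both times, with a median of -0.43 (camera adjusted p = 2.4e-21, and adjusted p = 0.28 with an estimated correlation). The list median was -0.63 at 24 h and -0.30 at 48 h. The lowest were CCNE2, a G1/S cyclin, at -0.81 (SE 0.51), ORC6, an origin recognition subunit, at -0.71 (SE 0.26), MCM6, a helicase subunit, at -0.66 (SE 0.31), and GINS2, a replication fork factor, at -0.65 (SE 0.33). By limma, 0 members passed over the list alone in the 8 arrays, where 1 had an unadjusted p under 0.05, and 19 did in the parental arrays. The 28 measured G2/M and mitosis genes were all lower, with a median of -0.29 (camera adjusted p = 1.4e-08, and adjusted p = 0.52 with an estimated correlation). They were led by CDK1, the mitotic kinase, at -0.47 (SE 0.40) and TTK, a spindle checkpoint kinase, at -0.45 (SE 0.56).

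**Figure D2:**
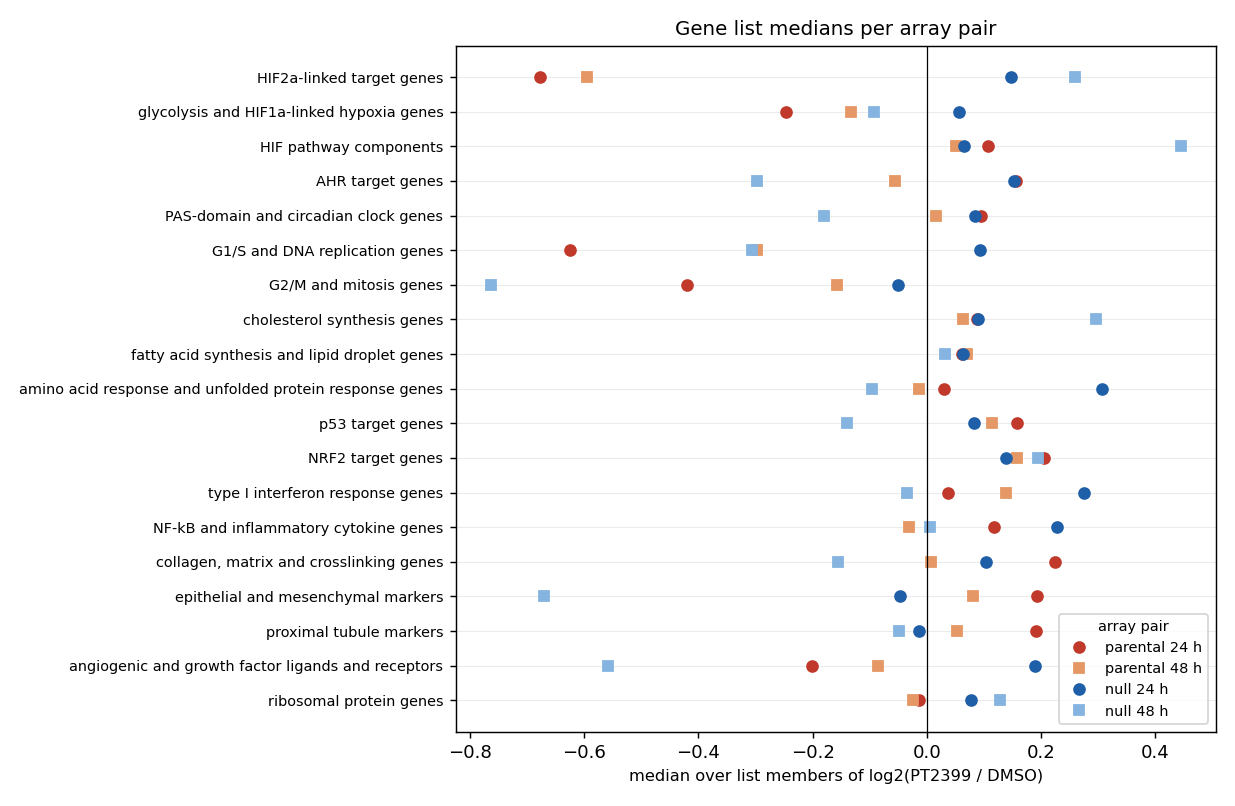
Median log2(PT2399/DMSO) over the members of each of 19 gene lists, 1 point per array pair, in red and orange for parental and in dark and light blue for null cells. The HIF2a-linked list lies at -0.68 and -0.59 in the parental pairs and at 0.15 and 0.26 in the null pairs.

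The angiogenic and growth factor list had 16 of 21 members lower, with a median of -0.17 (camera adjusted p = 1.5e-05, and adjusted p = 0.50 with an estimated correlation). Adjusted over the list alone EDN1, TGFA and VEGFA fell, and PDGFB, a platelet-derived growth factor chain, stood at -0.58 (SE 0.28). The NRF2 target list was the one higher list with all 8 arrays as deposited. By their means 17 of 18 members were higher, 10 of them at both times, with a median of 0.15 (camera adjusted p = 0.0021, and adjusted p = 0.31 with an estimated correlation). Its leading members were the aldo-keto reductases AKR1B10, AKR1C3 at 1.17 (SE 0.39) and AKR1C1 at 0.90 (SE 0.27), whose NRF2 link is not exclusive. In null cells the NRF2 list also had a median of 0.15, with 11 members higher and 7 lower. The difference between the genotypes did not pass for it (camera adjusted p = 0.60), so the rise is not shown to be particular to parental cells. Centring of each array on its median moved the median of all genes by -0.12 in parental cells, and the NRF2 list, whose camera call held, then had a median of 0.03 with 8 of 18 members lower.

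The other 13 lists did not pass camera in parental cells, and 9 lists had medians under 0.1 whose sign turned with centring: HIF pathway, AHR, PAS-domain, cholesterol, lipid, amino acid, interferon, matrix and epithelial and mesenchymal genes. Medians were 0.18 for p53 targets (camera adjusted p = 0.078), led by GDF15, a stress cytokine, at 0.93 (SE 0.25) and TP53INP1 at 0.85 (SE 0.27), and 0.10 for epithelial and mesenchymal markers (0.11), led by CDH6, a kidney cadherin, at 0.78 (SE 0.35). Epithelial and mesenchymal markers passed camera as higher with the parental arrays alone (camera adjusted p = 0.040, and adjusted p = 0.61 with an estimated correlation), and p53 targets after centring (0.037, and adjusted p = 0.63 with an estimated correlation). Without the filter the endothelial and leukocyte markers passed as higher (camera adjusted p = 0.045, and adjusted p = 0.73 with an estimated correlation). They were 0.09 for interferon response genes (camera adjusted p = 0.16), 0.15 for the 6 proximal tubule markers above the filter (0.27) and 0.10 for cholesterol synthesis (0.40). Ribosomal protein genes had a median of -0.02 (camera adjusted p = 0.49), and fatty acid and lipid droplet genes 0.09 (0.97), with HILPDA and PLIN2 lower and SCD, the stearoyl-CoA desaturase, at 0.64 (SE 0.23). The AHR target, PAS-domain and clock, and collagen and matrix lists had medians of 0.07, 0.09 and 0.09 (each camera adjusted p = 0.97), with BHLHE40, a hypoxia-linked repressor, at -0.64 (SE 0.23). The amino acid and unfolded protein response list at 0.03 and the NF-kB list at 0.13 (each camera adjusted p = 0.99) held TRIB3, a pseudokinase, at -0.95 (SE 0.33), CCL20, a chemokine, at -1.55 (SE 0.74) and LIF, a cytokine, at -0.85 (SE 0.31). The NF-kB mean of -0.03 and its test were opposite in sign to its median. The parental 24 h PT2399 array had a median intensity of 133.8 against 112 to 113 on the other 3 parental arrays, and the 24 h differences had an SD over genes of 0.386 against 0.199 at 48 h.

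**Figure D3:**
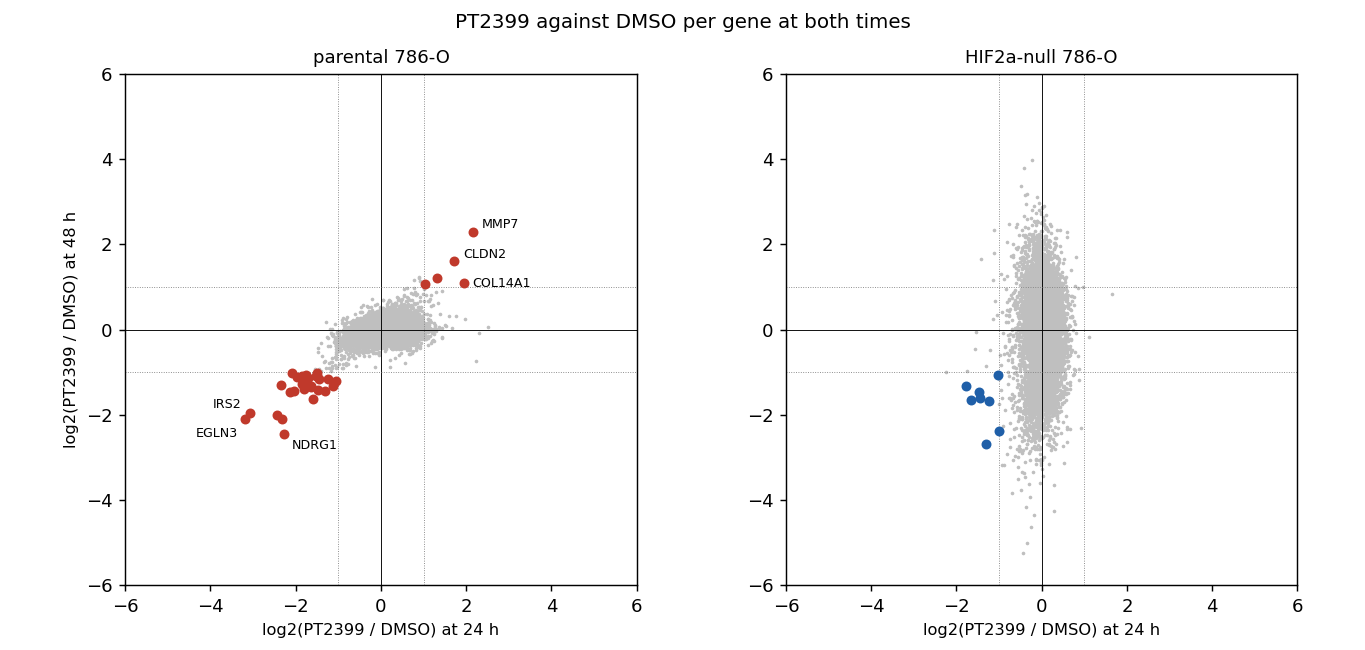
Log2(PT2399/DMSO) at 24 h against 48 h for each of 11050 genes, parental cells on the left and HIF2a-null cells on the right, with coloured points at least 2-fold changed in 1 direction at both times and dotted lines at 2-fold. There were 28 lower and 5 higher such genes in parental cells and 8 lower and 0 higher in null cells.

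The second comparison asked what PT2399 does in cells labelled null for its target. In null cells the HIF2a-linked list had 11 members higher and 7 lower, with a median of 0.22 (camera adjusted p = 0.54). EGLN3 stood at -0.07 (SE 0.34), NDRG1 at 0.42 (SE 0.25), ADM at 0.23 (SE 0.24) and CCND1 at 0.37 (SE 0.29). At 24 h, 27 of the 28 genes that were 2-fold lower in parental cells lay within 0.5 of 0 in null cells, with a median of 0.08 and CCL20 at 0.92 as the exception. At 48 h, on the array that stood apart, 12 of the 28 lay within 0.5 of 0, with a median of 0.05 and a range from -2.31 to 1.97. Less signal was left to fall in many of them, since 19 of the 28 were already at least 2-fold lower in null DMSO cells at both times. The EGLN3 intensities of 73 to 110 lay below the filter limit of 118. Whether the group as a whole lay near background was not tested. The G2/M and mitosis list was the one list past camera, with 23 of 28 members lower and a median of -0.40 (camera adjusted p = 0.00050, and adjusted p = 0.93 with an estimated correlation). Its median was -0.05 at 24 h and -0.76 at 48 h, and its leading members were CENPE, a mitotic kinesin, at -2.03 (SE 0.53) and HMMR, a spindle-associated protein, at -1.66 (SE 0.53).

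Genes 2-fold lower at both times in null cells numbered 8, where independent times would give 3.40, and 0 were higher. Named because they met this count, they included CYCS, cytochrome c, at -1.45, CWC25, a spliceosome factor, at -1.46, and CSRP2, a LIM protein, at -1.65, while 2 were small RNAs. Limma called 0 genes in null cells with a lowest adjusted p of 0.608, and 481 had an unadjusted p under 0.05, against 552.5 by chance. Among the largest mean differences of genes that the naming rule allows were EZHIP, an inhibitor of the Polycomb complex, at -2.05 (SE 0.56), UBLCP1 at -2.03 (SE 0.66), CUTA at 1.48 (SE 0.63) and NDUFA1, a complex I subunit, at 1.44 (SE 0.64). They came largely from the 48 h pair, as in NDUFA1 with 0.01 at 24 h and 2.87 at 48 h.

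The null 48 h PT2399 array correlated across genes with the other null arrays at 0.777 to 0.831, where those correlated among themselves at 0.940 to 0.983. Its difference from DMSO had an SD over genes of 0.928 against 0.240 at 24 h, and without the null 24 h arrays, when the null effect rests on this array, limma called 5137 genes. Without the null 48 h arrays it called 0, with 331 genes at an unadjusted p under 0.05, and the G2/M list was no longer past camera.

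The third comparison set the parental effect against the null effect, in the same model. The HIF2a-linked list differed by a median of -0.96, with 13 of 18 members lower in parental cells, 11 of them at both times (camera adjusted p = 4.2e-10, and adjusted p = 0.35 with an estimated correlation, fry adjusted p = 0.072). Adjusted over the list alone, 7 members passed by limma: NDRG1 at -2.78 (SE 0.35), EGLN3 at -2.57 (SE 0.48), whose null levels lay below the filter limit, ADM at -2.44 (SE 0.34), CCND1, SLC2A1, SLC7A5 and PLIN2. VEGFA at -1.24 (SE 0.48) and TGFA at -1.25 (SE 0.51) did not. The glycolysis and HIF1a-linked list differed by -0.22, with 16 of 25 members lower, 12 of them at both times (camera adjusted p = 0.0023, and adjusted p = 0.57 with an estimated correlation), led by DDIT4 at -1.87 (SE 0.39). The G1/S list differed by -0.39, with 28 of 31 members lower in parental cells (camera adjusted p = 9.5e-07, and adjusted p = 0.57 with an estimated correlation), led by GINS2 at -1.24 (SE 0.47). Only 13 of the 31 were lower in parental cells at both times, and the list medians at 48 h were close, at -0.30 in parental and -0.31 in null cells, so that the difference of medians came largely from 24 h.

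Over all genes limma called 0 for this difference, with a lowest adjusted p of 0.945. There were 192 genes at an unadjusted p under 0.05, against 552.5 by chance. Among genes outside these 3 lists were IRS2 at -2.79 (SE 0.55), MMP7 at 2.51 (SE 0.37) and IL18 at 2.35 (SE 0.95), the last with -2.82 in the null 48 h pair. A call in parental cells and none in null cells is therefore not by itself a difference between the genotypes for single genes outside the lists.

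Null and parental cells in DMSO were also compared, with no test, because the 2 were run as separate experiments. HIF2a-linked genes were lower in null cells, with a median of -0.38 at 24 h and -0.27 at 48 h, against -0.20 and -0.13 over all genes, which centring moved by -0.11 and 0.19, and 10 of 18 were lower at both times. These medians lay at percentiles 6.83 and 6.62 of 10000 random lists, so that lists picked at random were at times as low. NDRG1 stood at -3.02 and -2.75, EGLN3 at -2.97 and -2.95, and F3 at -2.44 and -2.79. VEGFA at -0.27 and 0.41 and TGFA at -0.21 and 0.68 were not lower at both times. Cholesterol synthesis genes had medians of -1.34 and -0.77, with 17 of 19 lower at each time, and G1/S genes -0.69 and -0.43. NF-kB and inflammatory genes were higher, with medians of 0.55 and 1.14. In all 517 genes were 2-fold lower and 344 2-fold higher at both times, among them the ribosomal protein gene RPL28, with intensities of 4696 and 97.8 at 24 h, and the isomerase gene PPIA, with 372 and 6423.

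The parental PT2399 effect was then set against the null-minus-parental difference in DMSO. All 28 genes that were at least 2-fold lower with PT2399 at 48 h were lower in null cells at 24 h, 22 of them at least 2-fold, with a median of -1.99. Over all genes 63.1% were lower and 9.33% were 2-fold lower. Of 86 genes at least 2-fold lower at 24 h, 65 were lower in null cells at 48 h and 29 were 2-fold lower, against 60.8% and 8.55% of all genes. Of 93 genes at least 2-fold higher at 24 h, 38 were higher in null cells at 48 h, with a median of -0.18, close to that of all genes, and of 9 at least 2-fold higher at 48 h, 6 were higher in null cells at 24 h. These counts use different DMSO arrays for the effect and the difference. Across all genes, which are not independent replicates, the mean effect and mean difference had r = 0.25 and a covariance of 0.0426. In 100 simulations of unchanged genes sharing the DMSO arrays, with the parental spread on all arrays, these were 0.498 and 0.0117. The simulated r follows from the shared arrays and equal noise, so it sets no level for the measured r. Only the covariances can be set side by side. With different DMSO arrays r was 0.0186 for the 24 h effect and 0.0811 for the 48 h effect.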

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

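All tests of explanations in this part were chosen after the result they bear on was seen, except that of other probe sets of a gene. The PT2399 effect differed between parental and null cells, by camera on the interaction, for 3 lists. The HIF2a-linked list differed by a median of -0.96 on the log2 scale, the G1/S and DNA replication list by -0.39 and the glycolysis and HIF1a-linked list by -0.22, none of which passed with an estimated correlation (adjusted p = 0.35, 0.57 and 0.57).

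The lower G1/S genes in parental cells were weighed further. Were the odd intensity distribution of the parental 24 h PT2399 array the whole cause, the 48 h pair would be near 0, and its list median was -0.297. An action of PT2399 that does not need HIF2a would lower the list in null cells, where the median was 0.0932 at 24 h, with 25 of 31 members higher. The list was already lower in null than in parental DMSO cells at 24 h, with a median of -0.69 and 28 of 31 members lower. The values therefore argue only against an action of equal size in both genotypes at that time. At 48 h the null median was -0.306, as low as in parental cells, with 17 members lower and 14 higher on the array that stood apart. There an action that does not need HIF2a cannot be told apart from the state of that array. A HIF2a-dependent slowing of growth, which may follow from lower CCND1, and a difference in cell density between the dishes stay open as hypotheses and were not tested.

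The null 48 h PT2399 array stood apart from all other arrays of its genotype. Quantile normalization left its difference from DMSO with an SD of 0.901, against at most 0.380 in the other pairs, which argues against scaling. Loss of small RNAs may be part of it. The test first set, their median over 108 small nucleolar and Cajal body RNA genes, left it undecided at -0.62. A test chosen after that, the SD without them, gave 0.914 over the other 10942 genes, against 0.928 with them. As 108 genes are too few to carry most of that SD, this test could not weigh their loss and leaves it undecided. It shows only that the spread was also present in the other genes. An action of PT2399 that does not need HIF2a would appear in parental cells at 48 h, where the median share of the change over 2910 genes was -0.0207. RNA quality, a different source of that RNA and an effect present in null cells after 48 h alone stay open and were not tested.

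Some genes differed many-fold between null and parental cells in DMSO, 28 of them by at least 8-fold at both times. Over these the median share of the gap moved by PT2399 in parental cells was -0.0148, which argues against the loss of HIF2a activity that PT2399 gives within 48 h, for these 28 as a set. It does not extend to genes just under this limit. EGLN3, with gaps of -2.97 at 24 h and -2.95 at 48 h, had PT2399 effects of -3.18 and -2.10. NDRG1, with gaps of -3.02 and -2.75, had effects of -2.27 and -2.46. Ribosomal protein genes argue against a shift of that whole class between the experiments. Over 63 of them, paralogues such as RPL10L and RPL3L included, the median size of the gap averaged over both times was 0.830 times that of their single changes from 24 h to 48 h. Averaging cancels gaps of opposite sign, so that this ratio can be understated. Yet 4 of the 63, among them RPL28 at -5.59 at 24 h, were at least 2-fold lower and 1, RPL37A, 2-fold higher at both times. A readout of single probe sets that differs between the experiments cannot be told apart from a true difference, because among 170 genes with a gap of at least 4-fold there were 4 with another probe set above the filter, with a median share of 0.0502, of which 3 did not show the gap there (shares of 0.13, -0.03 and -0.04) while the other, NPB, had identical values in both and so no second readout. Long-term adaptation or clonal differences of the null cells stay open and were not tested.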

How the results depend on the processing

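Alternatives chosen after seeing the data are those named as such among the methods, and the rest were planned. Counts of genes called by limma stayed at 0 in all 3 comparisons under the filters, probe set rule, scalings, eBayes priors, time terms, the added floor and a 1.5-fold limit. They changed with the arrays entering the fit. With the arrays of the genotype alone, whose own pairs then set the spread, 4 genes were called in parental and 14 in null cells. Leaving out 1 pair of arrays at a time gave 0 to 4 calls in parental cells, 0 to 5137 in null cells and 0 to 3477 for the difference. The highest 2 came without the null 24 h arrays, when the null effect rests on the odd array and the lone null pair is assumed to vary like the parental pairs. With 0 genes called to begin with, no call could be lost. Of 1142 values of named genes under the alternatives, 45 gained a call, 7 changed sign without a call and 1090 did neither. With scaling, the sign changes were LOX (-0.069) and CITED2 (8.4e-04) in parental cells after quantile normalization, and LOX (-0.10), ARNT (-0.048) and VHL (-0.024) after centring of each array. With a pair left out, CITED2 ranged from -0.10 to 0.065 in parental and EGLN3 from -0.34 to 0.20 in null cells, and the cause was not tested. A limit of 1.5-fold at both times gave 69 lower and 40 higher genes in parental and 58 lower and 19 higher in null cells. Without the filter there were 9 higher in parental cells and 34 lower and 3 higher in null cells, since more genes were counted. With an estimated correlation 0 lists were called in any comparison, and with fry 0. The estimates were at most 0.0056 for the HIF2a-linked, glycolysis and NRF2 lists, below the preset 0.01. Correlated members were therefore not what cost these 3 lists their calls. For the G1/S, angiogenic and G2/M lists the estimates lay between 0.16 and 0.53. Without the null 48 h arrays, 3 lists were called in null cells and 7 for the difference, where G2/M and mitosis genes went from a median of 0.16 to -0.27. Epithelial and mesenchymal markers were also called as higher for the difference after quantile normalization (camera adjusted p = 0.035, and adjusted p = 0.64 with an estimated correlation). For null against parental cells in DMSO, the HIF2a-linked median was -0.44 over the mean of both times and -0.27 at 48 h alone, and single times gave 1031 (24 h) and 945 (48 h) genes 2-fold lower and 674 (24 h) higher. The correlation of 0.25 between effect and difference became 0.196 after quantile normalization, and 0.0186 and 0.0811 with different DMSO arrays, which removes the shared arrays. Intensities near the filter limit of 118 hold unknown background, so that folds of genes below it on 1 side, such as EGLN3 with PT2399 and MMP7 in 48 h DMSO cells, can be understated.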

Other observations

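Parental cells changed between 24 h and 48 h without PT2399, with 1 array per time and no test. In both treatments 8 genes were at least 2-fold lower at 48 h and 2 were higher, named after their values were seen. The lower ones were MMP7, CLDN2, AKR1B10, AKR1C1, AKR1C3, CFI, IFI44L and PLXDC2, with MMP7 at -1.81 and CLDN2 at -1.64 in DMSO. All 8 were higher with PT2399 than with DMSO in parental cells, by 0.83 to 2.15 at 24 h and 0.58 to 2.29 at 48 h. Whether their rise with PT2399 and their fall with time are linked was not tested. The higher ones were ANKRD1, a mechanically induced nuclear factor, at 1.80 and PDCD1LG2, which encodes the immune ligand PD-L2, at 1.30. Interferon response genes had a median of -0.27 from 24 h to 48 h in parental DMSO cells, with 24 of 25 lower, and of 0.44 in null DMSO cells, with 20 of 25 higher. Cholesterol synthesis genes had a median of -0.36 in parental cells, with 16 of 19 lower, and of 0.01 in null cells, where centring of each array moved all genes by 0.29.

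The amino acid and unfolded protein response list stood higher in null than in parental DMSO cells, with medians of 0.42 at 24 h and 0.64 at 48 h and 17 and 22 of 25 members higher. For p53 targets 10 of 19 were higher at 24 h, with a median of 0.21 that became 0.10 after centring, and 15 at 48 h, with a median of 0.53. Without the null 48 h arrays, an alternative chosen after seeing the data that leaves 1 null pair assumed to vary like the parental pairs, 3 lists passed camera as higher with PT2399 in null cells. They were the amino acid and unfolded protein response list at 0.31 (limma camera adjusted p = 6.0e-06), the interferon list at 0.27 (6.7e-04) and the NF-kB list at 0.23 (0.036). With an estimated correlation each adjusted p was 0.99.

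Of the probe sets outside the gene tests, 3 with several genes and 2 unnamed here were at least 2-fold lower with PT2399 at both times in parental cells, and 0 were higher.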
